A study of Mus musculus with 4 samples.

How the data were processed

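Gene expression was measured in CD4 single-positive thymocytes of B6 mice, the T cell precursors that have completed CD4 lineage choice in the thymus. The LM arrays came from Cul3-floxed mice without the CD4-Cre transgene and the KO arrays from Cul3-floxed mice with it, with 2 arrays per group and 4 arrays in all. Per the labels, cells were sorted in the cold as negative for CD25, for the CD1d-PBS57 tetramer that marks NKT cells, and for the gamma delta T cell receptor. Total RNA was extracted with Trizol, amplified with the WT-Ovation Pico system and labelled with biotin, per the labels' protocols. The labels do not say that the 2 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

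The authors deposited 1 linear signal intensity per probe set and array, from 0.1 to 43129 over the 4 arrays. The deposited intensities had been scaled, since the mean of each array after trimming 2% of the values at each end was 500.0. The program that summarised probes into probe sets, its background correction and its detection calls are not given in the sources used here. Of 45101 probe sets, 64 controls were left out. Among the other 45037, the platform annotation gave 34945 a single gene symbol, 932 several and 9160 none, and only the first kind was named. Of these, 34741 matched the RefSeq gene table and 0 symbols had to be updated. The single-gene probe sets named 18193 genes. No genome came with the series, so probe positions within genes were not used here.

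Intensities were taken as log2(value + 16), which understates the changes of dim genes. Array medians on that scale were 7.42 and 7.28 for LM replicates 1 and 2 and 7.36 and 7.44 for KO replicates 1 and 2. They differed by more than the 0.1 allowed in advance, so the arrays were quantile normalized. Each gene was represented by the probe set with the highest mean over the 4 arrays. The background was set per array at the 95th percentile of 80 olfactory and vomeronasal receptor probe sets, a signal of 106, 92, 98 and 78 for LM 1, LM 2, KO 1 and KO 2. A gene was tested if it exceeded this level on at least 2 arrays, which kept 11255 genes and left out 6938. Where a gene lay below it on both arrays of 1 group, the fold is given as a lower bound, with the dim group raised to that level on each array. Array number and signal over background limit the precision, and the median standard error over genes was 0.22 on the log2 scale.

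KO minus LM differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with genotype as the only term. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and borrowed 9.96 from the other genes. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9. Before the data were examined, 30 gene lists were fixed from general knowledge of the field, and 749 of their 823 entries had a named probe set. The 26 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation, camera has only the 2 residual degrees of freedom, so its p can rise without a higher correlation. The lists share some members, so their tests are not independent.

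The genes named were also fixed in advance: Cul3, the 10 largest called differences in each direction with no overlap between the groups, up to 4 members of each list with the smallest p, and 19 genes of interest. Other genes named below, including the remaining called genes, were chosen after their values were seen. On 20 simulated sets of 11255 genes with 200 changed, built on the spread of these arrays, the test called 46.1% of 2-fold and 86.6% of 4-fold changes, and 5.59% of its calls were false. A shifted cell cycle list was called in 20 of these 20 sets with the preset correlation, in 14 by fry and in 0 with an estimated correlation. The simulated genes varied independently, with spreads drawn from the model that limma fitted. These rates therefore assume that model and are no check of it on these arrays, where genes may be correlated.

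Alternatives tried were no filter and a stricter filter on dim genes, no normalization and median centring, pseudocounts of 1 and 64, eBayes without the trend and with robust moderation, the mean of all probe sets, every probe set separately, the replicate number as a block, each array left out in turn, other thresholds, and lists without shared members. With 2 arrays per group there are 3 splits into 2 and 2, so no share of splits under 0.05 can be reached.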

Results

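The series compared the transcriptomes of sorted CD4 single-positive thymocytes from Cul3-floxed mice with and without the CD4-Cre transgene. It comprised 4 arrays, 2 labelled LM (Cul3-floxed without Cre) and 2 labelled KO (Cul3-floxed with Cre), each with signals for 45101 probe sets. Cre was meant to remove Cul3, the cullin scaffold of BTB-adaptor ubiquitin ligases. With no array from mice carrying Cre without floxed Cul3, effects of Cre itself and of Cul3 removal cannot be told apart. Correlations between arrays over the 11255 tested genes ran from 0.961 to 0.974, with 0.974 for the LM pair and 0.964 for the KO pair. The 3'/5' signal ratio of the Gapdh control was 2.63 and 2.93 on the LM arrays and 2.59 and 2.70 on the KO arrays. That of the beta-actin control was 0.908 and 0.961 on the LM arrays and 0.891 and 0.989 on the KO arrays.

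The targeted gene was examined first. The brightest Cul3 probe set read 5333 and 5724 on the LM arrays and 5380 and 5577 on the arrays labelled KO, a log2 difference of -0.01 ± 0.09 (SE, limma adjusted p = 0.994). Its 95% interval, -0.22 to 0.19, excluded a signal on the KO arrays below 86.1% of that on the LM arrays. The other 4 probe sets differed by 0.31, 0.07, -0.15 and -0.02, and none of the 5 was lower at the threshold. The lower limits of their 95% intervals were 97.7%, 70.5%, 65.3% and 73.4% of the signal on the LM arrays. Which exons were deleted and where the probe sets lie were not given in the sources used here, and a probe set outside the deleted part checks nothing. The genotype therefore rests on the labels, and each direction below is that of the arrays labelled KO.

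**Figure D1:**
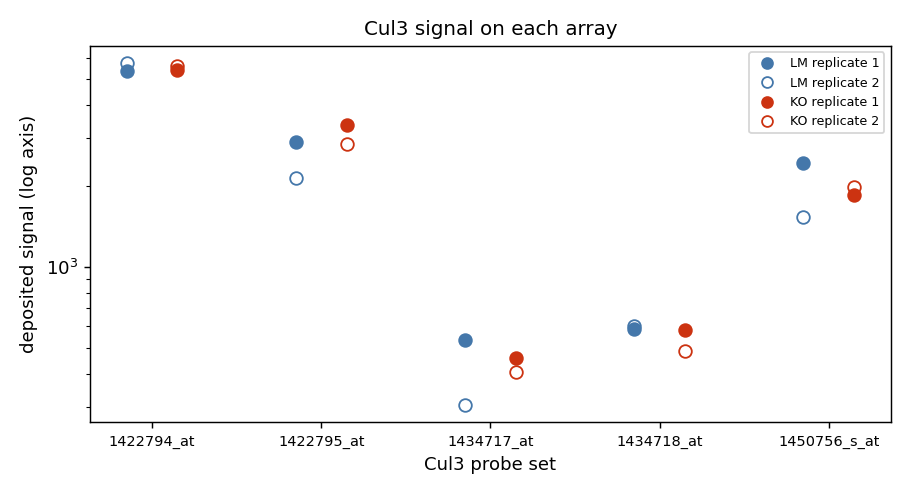
Deposited signal (log axis) of the 5 Cul3 probe sets (horizontal axis) on each of the 4 arrays, with LM in blue and KO in red, replicate 1 filled and replicate 2 open. The brightest probe set lies between 5333 and 5724 on all 4 arrays, with the groups interleaved.

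The main comparison asked which genes differ in RNA level between the genotypes. Among the named genes past the threshold, Cd55, the complement decay-accelerating factor, fell most, from 10.24 ± 0.33 on the LM arrays to 7.33 ± 0.28 on the arrays labelled KO (log2 mean ± SD, n = 2 each), a 7.47-fold difference. Mmp9, a secreted gelatinase, had the largest fitted rise among them: it was below background on both LM arrays and at 9.43 ± 0.28 (SD, n = 2) on the arrays labelled KO, at least 5.99-fold higher. In all, 15 genes rose and 16 fell on the arrays labelled KO, and 26 of the 31 differed by 2-fold or more. Without the filter on dim genes, and separately without the intensity trend in eBayes, 0 genes passed in limma, while 1247 of 18193 and 922 of 11255 genes lay at an unadjusted p below 0.05. At the settings fixed in advance 945 genes did, against 563 by chance.

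After Mmp9 (adjusted p = 0.00207), the called genes with the largest fitted rises in limma were Ptges3l (1.90 ± 0.27, log2 difference ± SE), Mid1 (1.88 ± 0.22), a microtubule-bound ubiquitin ligase, and Edaradd (1.79 ± 0.21), an adaptor of the ectodysplasin receptor. Egln3, a prolyl hydroxylase acting on hypoxia-inducible factor, rose by 1.72 ± 0.23, and Ctla2a, which resembles the propeptide of cysteine proteases and inhibits cathepsins, by 1.57 ± 0.16. The peptide transporter Slc15a1 rose by 1.54 ± 0.17, the Ras exchange factor Rasgrp4 by 1.46 ± 0.24, the chemokine receptor Ccr8 by 1.36 ± 0.18 and the protein kinase A anchor Akap2 by 1.35 ± 0.22. The other 5 were the thioredoxin reductase Txnrd1 (1.18), the serum response factor coactivator Mrtfb (1.14), the interleukin-25 receptor chain Il17rb (1.08), the cyclic AMP phosphodiesterase Pde7a (0.91) and the folate receptor family member Izumo1r (0.58). Adjusted p-values of the 15 ran from 0.00207 to 0.0392. Median centring ended the call of Izumo1r (0.53). Of the probe sets above background, 2 of 2 were higher for Mid1 and Akap2, 4 of 5 for Edaradd and 1 of 2 for Ptges3l. Averaging all probe sets of a gene, also those below background, ended the calls of Ptges3l (0.60), Mid1 (0.71), Edaradd (0.92), Akap2 (1.33) and Mrtfb (0.29). Leaving out KO replicate 1 ended those of Txnrd1 (0.93) and Izumo1r (0.54), and leaving out KO replicate 2 those of Rasgrp4 (1.39), Akap2 (1.21), Mrtfb (1.04) and Il17rb (0.82).

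Among the genes that fell, Cd55 (-2.90 ± 0.25, adjusted p = 0.000895 in limma) was followed by the receptor phosphatase Ptprv (-1.90 ± 0.32), the leucine-rich repeat adhesion molecule Amigo2 (-1.61 ± 0.19) and Cdca3 (-1.48 ± 0.24), a factor in mitotic entry. Topoisomerase Top2a (-1.44 ± 0.18), the kinetochore genes Cenpe (-1.41 ± 0.22) and Cenpf (-1.21 ± 0.20), the spindle motor Kif11 (-1.25 ± 0.17) and Ube2c (-1.23 ± 0.17), an E2 enzyme of the anaphase-promoting complex, also fell. So did Rab4a (-1.41 ± 0.25), a small GTPase of recycling endosomes. The other 6 were the clathrin adaptor subunit Ap1s3 (-1.20), cyclin Ccna2 (-1.11), Uhrf1 (-1.09), which acts in maintenance DNA methylation, linker histone H1f4 (-0.98), the proliferation marker Mki67 (-0.86) and galectin Lgals1 (-0.71). Of the probe sets above background, 2 of 2 were lower for Top2a, Cenpe and Cenpf and 1 of 1 for Amigo2. Averaging all probe sets, also those below background, ended the calls of Top2a (-0.22), Amigo2 (-1.09), Cenpe (-0.90), Cenpf (-0.76), Ccna2 (-0.92) and Uhrf1 (-0.79), and put Cdca3 below background. Leaving out LM replicate 1 ended the call of Uhrf1 (-1.03), LM replicate 2 that of Ptprv (-1.62), KO replicate 1 those of Cenpf (-1.13) and Rab4a (-1.04), and KO replicate 2 those of Ccna2 (-1.05), H1f4 (-0.79) and Uhrf1 (-1.06).

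**Figure D2:**
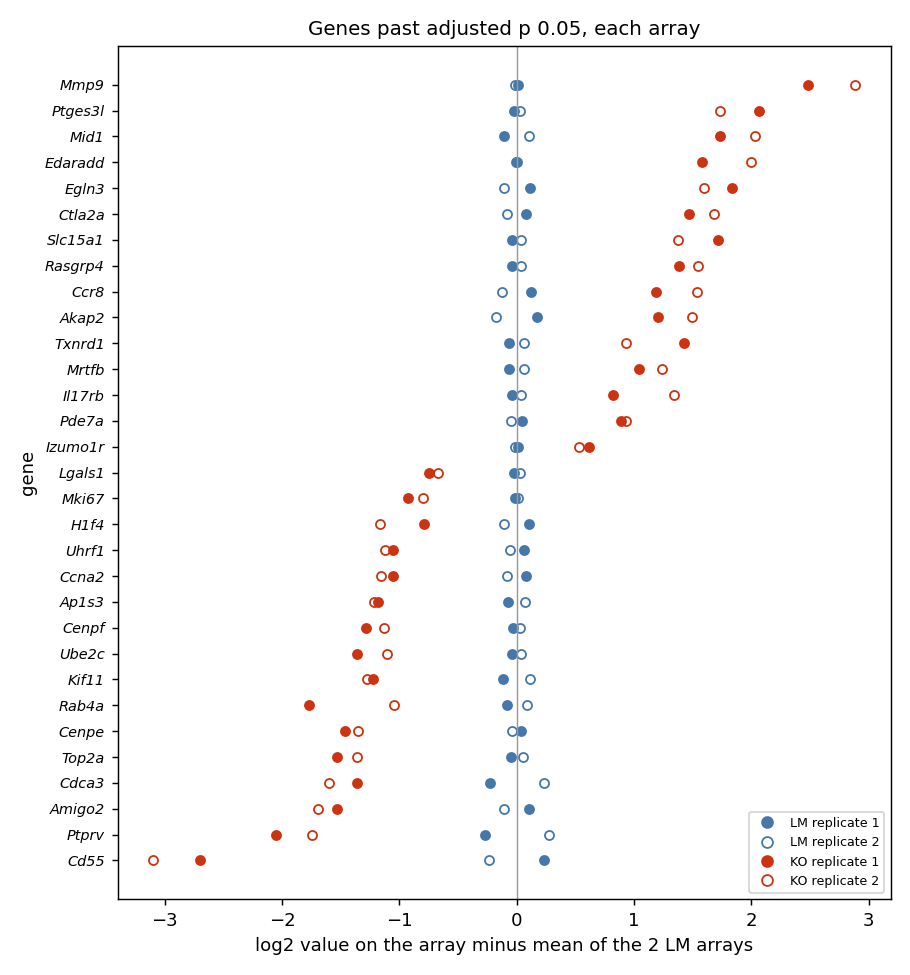
The 31 genes past the limma threshold (vertical axis), each array drawn as its log2 value minus the mean of the 2 LM arrays (horizontal axis), LM in blue and KO in red, replicate 1 filled and replicate 2 open. For each gene, both KO points lie beyond both LM points, from Cd55 at -2.90 to Mmp9, whose LM values lie below background.

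More genes were called when any 1 array was left out, in fits that assume the lone array to vary like the other group. With either LM array left out, the degrees of freedom borrowed from other genes were infinite, so each gene's own spread did not count. The added calls are therefore no sign that an LM array hid differences. The same holds for genes given below as passing without an LM array. Median centring gave 38 higher and 43 lower, and 30 of its 81 calls were among the 31. The groups did not overlap for 37.4% of all genes tested, against 33.3% by chance with 2 arrays each. None of the 24 called genes named by the rule moved by over 1.5 times when 1 array was left out, while 55 of the 105 uncalled ones did. A call requires a small replicate spread next to the difference, so this contrast follows from the selection and is no separate sign of stability.

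Cell cycle genes formed the list with the largest shift. Of 47 tested members 44 were lower on the arrays labelled KO, 8 fell over all genes tested, and 27 fell and 1 rose adjusted over the list alone. The median difference was -0.56, with Mki67, Top2a, Kif11 and Ube2c as the leading members. The list passed limma's camera with the preset correlation (adjusted p = 3.28e-27), while its adjusted p was 0.336 with an estimated correlation and 0.101 by fry. None of the 26 lists passed with an estimated correlation, where 1 lay at an unadjusted p below 0.05, and none by fry, where 7 did. Camera with an estimated correlation also called the shifted cell cycle list in 0 of the 20 simulated sets. A list that does not pass it, here and below, may therefore still be shifted.

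Regulatory T cell markers were higher, with a median of 0.46 over 16 tested members of which 15 were positive. Izumo1r alone rose over all genes, and 4 rose adjusted over the list alone. Il2ra, which encodes the CD25 chain that the sort selected against, differed by 0.72 ± 0.19 (adjusted p = 0.221), the Ikaros family factor Ikzf2 by 0.49 ± 0.13 (adjusted p = 0.245) and neuropilin Nrp1 by 1.01 ± 0.31 (adjusted p = 0.330). Foxp3, the lineage factor of these cells, differed by 0.48 ± 0.34 (adjusted p = 0.804), or by -0.09 without KO replicate 1 and 1.04 without KO replicate 2. The list median was 0.27 with probe set means and 0.319 or above in each of the fits without 1 array. Without LM replicate 2, Nrp1 passed the threshold at 1.35, against 0.67 without LM replicate 1. Camera gave the list an adjusted p of 1.60e-06 with the preset correlation and an adjusted p of 0.336 with an estimated correlation.

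Lists of helper T cell programs were also higher. For the follicular helper program (26 tested, median 0.15) the camera adjusted p was 0.00366, or an adjusted p of 0.392 with an estimated correlation. Izumo1r rose over all genes and 6 members adjusted over the list alone, while the AP-1 family factor Batf differed by 0.78 ± 0.16 (limma adjusted p = 0.0776), the ATP-gated channel P2rx7 by 0.68 and the signalling adaptor Sh2d1a by 0.58. Its lineage factor Bcl6 differed by 0.29 ± 0.19 (adjusted p = 0.786), or by 0.13 without KO replicate 1 and 0.45 without KO replicate 2, Pdcd1 by 0.84, Il21 by 0.64 and Icos by -0.06 (-0.14 and 0.02 without these arrays), and the receptor Cxcr5 was below background on every array. For helper lineage regulators (24 tested, median 0.18, adjusted p = 0.00366, or an adjusted p of 0.336 with an estimated correlation) 0 members rose over all genes and 5 adjusted over the list alone. Its leading members were Batf, the interleukin-12 signal transducer Stat4 (0.91, adjusted p = 0.103), Ikzf2 and the nuclear receptor Rora (0.69). Zbtb7b, the CD4 lineage factor, differed by 0.29 (adjusted p = 0.722), or by 0.175 without LM replicate 2. Leaving out KO replicate 2 ended the call of the follicular helper list, with a median of 0.07, against 0.09 with median centring, and leaving out LM replicate 2 brought Batf past the threshold at 0.87.

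The innate-like program linked to PLZF (25 tested, median 0.18) had a camera adjusted p of 0.00563, or an adjusted p of 0.530 with an estimated correlation. Il17rb rose over all genes and 3 members rose adjusted over the list alone, with Rora, the adhesion receptor Cd44 (0.89) and Il18r1 (0.61) next. Zbtb16, which encodes PLZF, differed by -0.49 ± 0.36 (adjusted p = 0.806). Chemokine and trafficking receptors (22 tested, median 0.17, adjusted p = 0.00617, or an adjusted p of 0.336 with an estimated correlation) held Ccr8, which rose, and 4 members that rose adjusted over the list alone. Cxcr2, below background on both LM arrays, was at least 1.37-fold higher with an adjusted p of 0.144, and Ccr4 differed by 0.59. The PLZF-linked median ran from 0.02 without LM replicate 1, where the list was not called, to 0.41 without LM replicate 2, and was 0.32 without genes shared with other lists of the study. The receptor median ran from 0.12 without LM replicate 1 to 0.43 without KO replicate 1. The receptor list was not called without KO replicate 2, nor with the stricter filter on dim genes, where its median was 0.118. Cd44 (1.20), Ccr4 (0.70) and Cxcr2 passed without LM replicate 2, while Cd44 differed by 0.58 and Il18r1 by 0.38 without LM replicate 1.

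Targets of NRF2, the antioxidant factor that Cul3 and Keap1 mark for degradation, were higher as a list (25 tested, median 0.18, adjusted p = 0.00366, or an adjusted p of 0.336 with an estimated correlation). Txnrd1 rose over all genes, and 2 members rose adjusted over the list alone. Glutathione reductase Gsr differed by 0.53, the glutamate-cysteine ligase subunits Gclm and Gclc by 0.62 and 0.41, Nqo1 by 0.73 ± 0.38 (adjusted p = 0.684) and Hmox1 by -0.12 ± 0.52. Keap1 itself differed by -0.09, or by 0.04 without KO replicate 2. Nqo1 differed by 0.47 without KO replicate 1, Gclc by 0.26 without LM replicate 1 and, with probe set means, Gsr by 0.32 and Gclm by 0.25, the 2 probe sets of Gclm differing in sign. The list median ran from 0.09 without LM replicate 2 to 0.28 without KO replicate 1 and was 0.06 with probe set means, and Hmox1 ran from -0.69 without KO replicate 2 to 0.45 without KO replicate 1.

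Mature single-positive and egress genes were called lower by camera and recently selected thymocyte genes higher. In the mature list (24 tested, median -0.07, adjusted p = 0.00366, or an adjusted p of 0.530 with an estimated correlation) Cd55 fell over all genes and 3 members fell adjusted over the list alone. Slfn1 differed by -0.33, Ms4a6b by -0.27, Klf2, a regulator of thymic egress, by -0.48 (adjusted p = 0.393) and Ccr7 by -0.25. In the recently selected list (24 tested, median 0.11, adjusted p = 0.00548, or an adjusted p of 0.336 with an estimated correlation) 0 members rose over all genes and 1 adjusted over the list alone. The nuclear receptor Nr4a2 differed by 0.87, the activation marker Cd69 by 0.56 (adjusted p = 0.427) and Egr1 by -0.29. The mature list was not called without LM replicate 1, and its median ran from -0.17 without LM replicate 2 to -0.02 without KO replicate 2. The mature median was -0.12 with median centring, and neither the mature nor the recently selected list was called without the eBayes trend. The recently selected list was not called without KO replicate 2, with a median of 0.08, and its median was 0.055 with median centring and 0.19 with probe set means. Nr4a2 differed by 0.55 without KO replicate 2 and by 0.53 with probe set means. Cd69 passed without LM replicate 2 (0.67) and without KO replicate 1 (0.95) and differed by 0.16 without KO replicate 2, and Ccr7 passed without LM replicate 2 (-0.47) and differed by -0.04 without LM replicate 1.

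**Figure D3:**
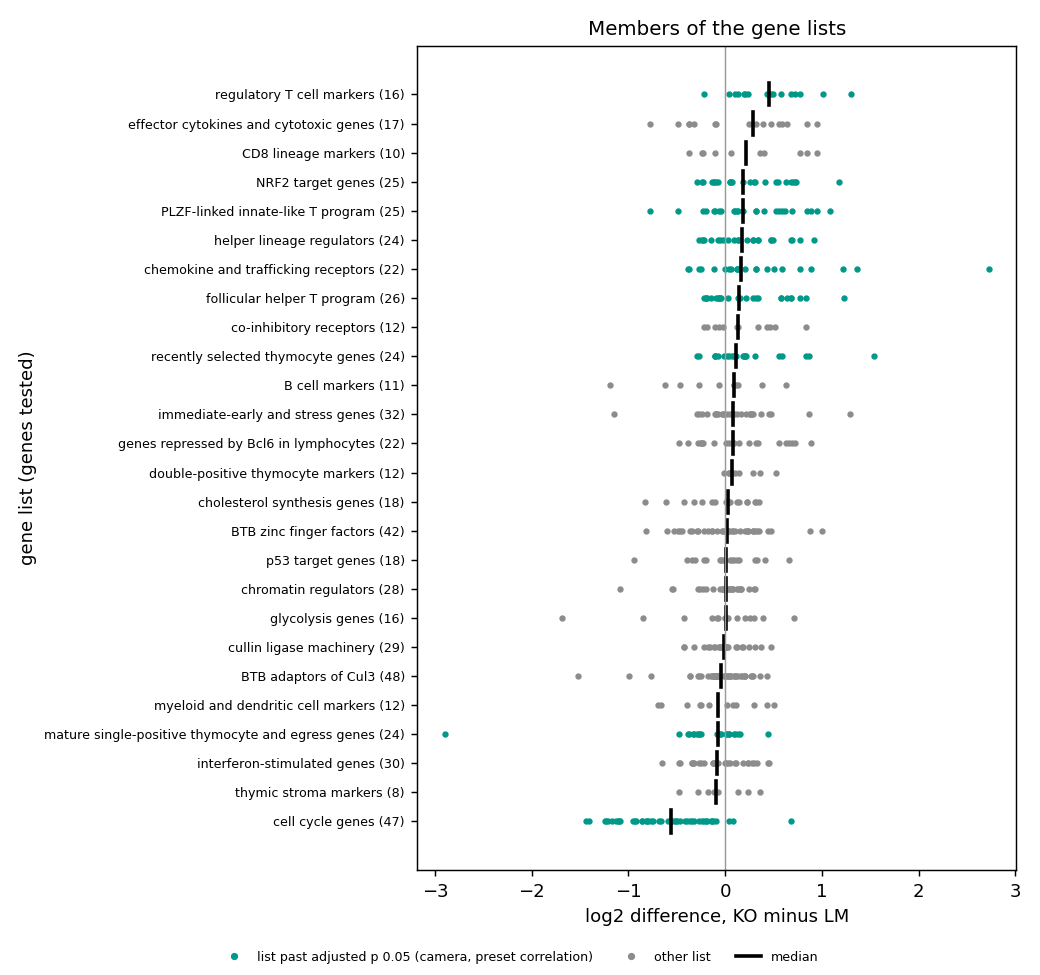
Log2 differences, KO minus LM (horizontal axis), of the tested members of the 26 gene lists (vertical axis, members tested in brackets), each point a gene and each bar the list median, with the 9 lists past camera's threshold at the preset correlation in green. Cell cycle genes lie lowest (median -0.56) and regulatory T cell markers highest (0.46), while other medians lie between -0.10 and 0.29.

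The remaining lists did not pass. Medians were -0.01 for cullin ligase machinery (29 tested), -0.04 for BTB adaptors of Cul3 (48), 0.02 for BTB zinc finger factors (42) and 0.08 for genes repressed by Bcl6 (22), with adjusted p-values of 0.845, 0.788, 0.845 and 0.265. They were 0.29 for effector cytokines and cytotoxic genes (17), 0.13 for co-inhibitory receptors (12), 0.08 for immediate-early and stress genes (32) and -0.08 for interferon-stimulated genes (30), with adjusted p-values of 0.265, 0.318, 0.190 and 0.190. These medians depended on single arrays, from 0.02 without LM replicate 1 to 0.32 without KO replicate 1 for effector genes, from 0.01 without KO replicate 2 to 0.20 without KO replicate 1 for co-inhibitory receptors, and from -0.01 without LM replicate 1 to 0.14 without LM replicate 2 for immediate-early and stress genes. Leaving out single arrays also moved cullin ligase machinery from -0.04 without KO replicate 1 to 0.06 without KO replicate 2, BTB adaptors from -0.03 without LM replicate 2 to -0.01 without LM replicate 1, BTB zinc finger factors from -0.01 without KO replicate 2 to 0.07 without KO replicate 1, and genes repressed by Bcl6 from 0.01 without LM replicate 1 to 0.11 without KO replicate 2. Among members of these lists, the phosphatase Dusp4 differed by 1.29 (limma adjusted p = 0.0776) and Ifit3 by -0.66 (adjusted p = 0.190). Dusp4 passed without LM replicate 1, LM replicate 2 or KO replicate 2, and Ifit3 without LM replicate 2 (-0.81). Immediate-early and stress genes passed with probe set means (median 0.12) and with separate probe sets (0.09), genes repressed by Bcl6 with separate probe sets (0.12), and interferon-stimulated genes without KO replicate 2 (-0.115), with a median of 0.004 without KO replicate 1. For p53 targets (18), glycolysis (16), cholesterol synthesis (18) and chromatin regulators (28) the medians lay within 0.03 of 0, at 0.01, 0.01, 0.03 and 0.01, and adjusted p-values were 0.795 to 0.978. With median centring the medians of BTB zinc finger factors, glycolysis genes and chromatin regulators were negative, at -0.04 each. For p53, glycolysis, cholesterol and chromatin lists and for B cell and myeloid markers, median, mean and camera direction did not all share a sign.

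Markers of cells that the sort could have let through were compared in the same way. Double-positive thymocyte markers had a median of 0.07 (12 tested), CD8 lineage markers 0.21 (10), B cell markers 0.09 (11), myeloid and dendritic cell markers -0.07 (12) and thymic stroma markers -0.10 (8), with camera adjusted p-values of 0.265, 0.190, 0.845, 0.978 and 0.788. With 1 array left out, double-positive markers ran from 0.02 (without KO replicate 2) to 0.26 (without KO replicate 1), CD8 markers from 0.05 (without KO replicate 1) to 0.40 (without KO replicate 2) and stroma markers from -0.10 (without LM replicate 1) to 0.06 (without KO replicate 2). B cell markers ran from -0.16 (without LM replicate 2) to 0.115 (without KO replicate 1) and myeloid markers from -0.29 (without LM replicate 1) to 0.12 (without KO replicate 1). Cd4 differed by -0.14 and Cd8a by 0.07, or by -0.22 without KO replicate 1. Gamma delta T cell, natural killer cell, erythroid and sex-linked lists had 3 tested members each, too few for a list test, with medians of 0.10, 0.02, 0.05 and 0.03. The Y-linked Eif2s3y differed by -0.17, or by -0.07 without KO replicate 1, and Xist was below background on every array, with its highest signal at 71.9.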

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

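The tests of the unnamed probe sets, of the exchanged arrays, of the Cul3 probe sets and of markers following Foxp3 were chosen after the results were seen, as was the use of the double-positive, NRF2 and mature-stage lists as tests of an explanation, while these list tests themselves and the tests of scaling were chosen before.

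Signal differences also appeared in probe sets that the comparison of named genes left out. Of 5121 tested probe sets without a single gene name here, 4 were called higher and 4 lower on the arrays labelled KO when all probe sets were fitted together in limma. In 1 of the 4 higher ones (adjusted p = 1.30e-05) the signals were 6.2 and 35.8 on the LM arrays, below background, and 2168 and 2347 on the arrays labelled KO, at least 19.7-fold higher. Its fitted log2 difference of 6.01 depends on the pseudocount and is no measure of size. The table used here gives it no gene, so no explanation was tested.

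Cul3 itself was not lower on the arrays labelled KO. At the fixed settings an exchange of 1 LM with 1 KO array is argued against. The 2 other splits of the arrays called 0 genes each there, against 31 for the labelled split. Without the dim filter or the eBayes trend the labelled split also called 0, and the other splits were not tried. Besides, 3 splits are too few to weigh chance, and an exchange of both pairs was not tested. That the probe sets lie outside the deleted part stays open, because 0 of the 5 were called lower and probe positions were not used here. Less ligase activity without less RNA at these probe sets may also hold: NRF2 targets had a median difference of 0.183, or 0.061 with probe set means. Their camera adjusted p was 0.00366 with the preset correlation and 0.336 with an estimated one. The estimate, -0.019, lay below the preset 0.01, so a higher correlation is not what raised p. With an estimated correlation, camera has only the 2 residual degrees of freedom. That test cannot decide the question, since it called 0 of 20 simulated cell cycle lists that were shifted.

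Cell cycle genes were lower as a list, with a median of -0.564. The list passed camera with the preset correlation, but not with an estimated one (adjusted p = 0.336) or by fry (adjusted p = 0.101). A loss of double-positive thymocytes that lowers their markers as much as the cell cycle genes is argued against, because these markers did not fall. The marker median was 0.069, or from 0.018 without KO replicate 2 to 0.259 without KO replicate 1. Its SE of 0.047 was taken over the 12 markers and does not measure the spread between arrays. A loss too small to move these markers stays open, since some of them, such as Rag2, lay near background. The 2 other scalings moved the median of all genes only from 0.002 to 0.004 and -0.046. That is too little to account for the cell cycle shift, whose median was -0.573 and -0.622 under them. Fewer late mature cells could contribute and stays open: mature-stage genes had a median of -0.074. Camera with an estimated correlation gave them an adjusted p of 0.530. It cannot decide the question, since it called 0 of 20 simulated cell cycle lists that were shifted. The genotype named by the design also stays open, without telling removal of Cul3 from the presence of Cre.

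Regulatory T cell markers were higher as a list, with a median of 0.456. Camera called them with the preset correlation, but not with an estimated one (adjusted p = 0.336), nor did fry (adjusted p = 0.134). The 2 other scalings moved the median of all genes too little to account for the marker shift, whose median was 0.424 and 0.474 under them. Probe set means lowered it to 0.267. More regulatory T cells among the sorted cells may account for part of it, although the sort removed CD25-positive cells. Between the KO replicates, Foxp3 differed by 1.122 and the other 15 markers by a median of 0.082 (SE over markers 0.091). Between the LM replicates the values were 0.671 and 0.032 (SE over markers 0.149), a spread too wide in LM to exclude that share. These SEs do not measure the spread between arrays. A change of expression within the sorted cells that follows the genotype stays open too.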

How the results depend on the processing

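Every alternative here was chosen before the data were examined, and the causes of the changes were not tested unless stated. Genes higher and lower on the arrays labelled KO numbered 15 and 16 at the fixed settings. They numbered 0 and 0 without the dim filter, where 18193 genes were tested, 0 and 0 without the eBayes trend, 25 and 21 with the stricter filter, 25 and 21 without normalization, 38 and 43 with median centring, and 25 and 24 at an adjusted p of 0.10. Pseudocounts of 1 and 64, robust moderation, probe set means, separate probe sets and the 2-fold limit left both counts within 1.5 times, from 13 to 21 higher and 12 to 21 lower. The replicate numbers are shared by the groups without a stated meaning, and replicate differences correlated at -0.0171 between genotypes. With a replicate block, 21 genes were higher and 22 lower, all 31 calls among them. Leaving out 1 array gave 16 to 56 higher and 24 to 41 lower, assuming that the lone array varies like the other group, and 19 of the 31 genes stayed called each time. Probe set means kept 19 of the 31. No called gene changed sign without an array, but none could, since the groups did not overlap for any of the 31. Of 26 lists, 9 were called at the fixed settings and 7 to 11 elsewhere, except 0 with an estimated correlation and 0 by fry. Cul3 had 0.041 with probe set means, and -0.053 to 0.032 without single arrays. Of 129 named genes, 77 kept direction and side under each setting that tested them, 15 to 17 settings per gene, and 18 reversed, none of them called. Median centring gave -0.016 for Tyrobp, -0.015 for Tfrc and -0.023 for Uty. Probe set means gave 0.24 for Zbtb17, 0.065 for Prf1, -0.086 for Tfrc, -0.058 for Uty, -0.029 for Cd8a and 0.214 for Keap1. Without single arrays the ranges were -0.197 to 0.394 for Cd163l1, -0.122 to 0.328 for Mns1, -1.435 to 0.183 for Ighm (lowest without KO replicate 1, adjusted p = 0.0262 in limma), -1.365 to 0.029 for Csf1r, -0.223 to 0.008 for Prf1, -0.434 to 0.478 for Tyrobp, -0.944 to 0.438 for Alas2, -0.186 to 0.279 for Tfrc, -0.243 to 0.722 for Aire, -0.076 to 0.277 for Kdm5d, -0.128 to 0.186 for Uty, -0.219 to 0.35 for Cd8a, -0.086 to 1.036 for Foxp3, -0.143 to 0.023 for Icos, -0.685 to 0.453 for Hmox1 and -0.225 to 0.039 for Keap1. For 7 lists, none of them called, the direction given by camera reversed in some settings, in part without a change of sign in the median. Chromatin regulators had medians of 0.008 without normalization, -0.041 with median centring, 0.012 without the trend, -0.033 with probe set means and -0.027 to 0.063 without single arrays. Glycolysis genes had -0.043 with median centring and 0.003 to 0.13 without single arrays, and myeloid markers -0.072 without the trend and -0.29 to 0.119 without single arrays. Cullin ligase machinery had 0.002 with probe set means and -0.001 with separate probe sets, and B cell markers -0.064 with probe set means and -0.156 to 0.115 without single arrays. Without single arrays, p53 targets ran from -0.13 to 0.1 and cholesterol synthesis genes from -0.047 to 0.12. Some genes passed only elsewhere: Batf with the stricter filter, without normalization, with probe set means and without LM replicate 2, and Dusp4 with the stricter filter, without normalization, with median centring, with the replicate block and without LM replicate 1, LM replicate 2 or KO replicate 2. Cxcr2 passed with median centring and without LM replicate 2, Cd44, Ccr4, Ifit3, Nrp1 and Ccr7 without LM replicate 2, Cd69 without LM replicate 2 and without KO replicate 1, and Srebf2 (-1.433) without KO replicate 1. Immediate-early and stress genes passed as a list with probe set means and with separate probe sets, genes repressed by Bcl6 with separate probe sets and interferon-stimulated genes without KO replicate 2. Outside the fits without 1 array, list medians moved by over 1.5 times in at least 1 setting for 22 of the 26 lists. The mature and recently selected lists were not called without the trend, nor the receptor list with the stricter filter. Signal over background limits the dim genes, whose inclusion ended all calls.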

Other observations

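The family tests below and the comparison of maturation lists were chosen after the results were seen, and the scan of chromosome segments before.

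Families of genes outside the fixed cell cycle list were examined too. Condensin and SMC genes, which compact chromosomes, had a median difference of -0.19 over 12 genes, 11 of them negative, led by Ncapg (-1.05 ± 0.20, SE, limma adjusted p = 0.0612). Cell division cycle associated genes had a median of -0.36 over 7, with Cdca5 at -1.14 and Cdca8 at -0.97 beside Cdca3, and centromere proteins one of -0.22 over 16, with Cenpk at -0.82 and Cenph at -0.80. Cdca3 was the only member of these 3 families called over all genes. The 3 had camera adjusted p-values of 0.00171, 0.000469 and 0.0203 at the preset correlation and 0.507 each with an estimated one. Because 14 families were tried, several of them picked for members that stood out, these p-values are not a separate test that cell division genes fell.

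The other 11 families did not pass camera at the preset correlation. Kinesins had a median of -0.01 over 21 genes, although Kif22 lay at -0.76 (adjusted p = 0.112). Medians were -0.07 for histone genes (18), 0.02 for proteasome subunits (47), 0.01 for ribosomal proteins (50), 0.01 for TNF receptors (14), 0.18 for interleukin receptors (23), 0.08 for dual-specificity phosphatases (15), -0.05 for RGS genes (11), -0.06 for MHC genes (16), -0.06 for mitochondrial complex I (44) and 0.16 for thioredoxin genes (15). The smallest of their camera adjusted p-values was 0.0679, for thioredoxin genes.

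A hypothesis is that the arrays labelled KO hold a larger share of less mature cells. The median difference of 24 recently selected genes exceeded that of 24 mature genes by 0.182 (two-sided permutation of genes between the lists, p = 0.00851, 100000 resamples). The comparison was chosen after camera had called these lists in opposite directions, so it restates those calls and decides nothing. The share of less mature cells stays open, as does regulation within cells.

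A second hypothesis was a chromosome segment that differs between the genotypes, as may remain around an engineered locus. Over 11233 placed genes, 294 lay at an unadjusted p below 0.01. The fullest window of 20 neighbouring genes held 4 of them, and shuffled gene orders gave a median of 4 for their fullest window (permutation p = 0.949, 2000 orders). No window thus stood out. A segment in which few genes changed would not stand out either, so the scan cannot exclude one. Both groups were Cul3-floxed, so the floxed Cul3 locus was present in both. The CD4-Cre transgene was in the KO group alone, and its position was not used here. Probe sets without a gene name were not placed, so the scan left them out. Windows of 4 were on chromosome 19, with Ifit3, Ifit1, Kif11 and Cep55, and on chromosome 4, with Smc2, Abca1, Tmem245 and Txn1.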
